A study of Mus musculus with 2 samples.

How the data were processed

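The study measured messenger RNA by RNA sequencing in 4T1 cells, a mouse mammary carcinoma line, grown alone or with M2 macrophages. The 4T1 cells sat in the lower chamber and the macrophages in the upper chamber of a transwell system for 3 days, per the labels' protocols. Total RNA of the 4T1 cells was extracted with TRIzol and treated with DNase I before libraries were made with standard Illumina methods, per the labels' protocols. There were 2 libraries, 1 per group, and the series describes itself as unreplicated. The culture of the control cells, with or without an empty upper chamber, is not given in the sources used here. The group of each library was taken from its treatment label. The title of the co-culture library names the cells 4T2, while its treatment label and the column of the deposited table name them 4T1. The treatment label was followed, and the identity of the cells was not verified from the data.

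The authors deposited 1 table of TPM values (a length-normalised transcript abundance) with 1 column per library. TPM divides each gene's reads by its transcript length and scales every library to the same total. The submitters' processing notes name HISAT2 2.1.0, RSEM 1.2.31 and the genome build GRCm38.p5, without giving their roles. The annotation release, the strandedness of the libraries and any filter are not given in the sources used here. The table had 52796 rows, of which 51912 carried Ensembl gene identifiers and 884 carried identifiers of the MSTRG form, the prefix that the assembler StringTie gives to loci it builds from reads. TPM values were rounded to 2 decimals. TPM keeps no information on sequencing depth, so the depth of both libraries is unknown here and no counting intervals or detection floors were computed. RSEM divides reads that match several genes between them, so values of paralogs, pseudogenes and overlapping genes are uncertain.

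Symbols came from a table of GENCODE M21 names (assembly GRCm38), which held 51633 of the Ensembl identifiers, and positions and biotypes came from the GENCODE M21 annotation. The identifiers without a symbol numbered 279. Positions are 1-based on GRCm38. All gene-level statements use rows with Ensembl identifiers, a choice made after the table was seen, and the assembled loci are described apart.

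From the deposited values a log2 ratio was computed per gene as log2((co-culture TPM + 1)/(control TPM + 1)), with a pseudocount of 1. This scale understates the change of genes with low values. A gene counted as detected when its mean TPM over both libraries was at least 1. Genes were described as 2-fold higher or lower when the log2 ratio reached 1 or -1. With 1 library per group no test between groups can be made, no p-values or standard errors are given, and every difference compares these 2 libraries only. Gene lists were fixed before the data were examined, 37 in all. For each list with at least 3 detected members, the median log2 ratio was set against 10000 random lists of the same size, drawn from 20 bins of mean expression. A list was said to stand apart when its median lay at or below the 2.5th or at or above the 97.5th percentile. By chance 5% of lists of unrelated genes do so. The percentile describes these libraries and is not a p-value, since genes are not replicates.

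The genes named were fixed by rule before the data were examined. The rule took the 12 largest ratios in each direction among genes with a mean TPM of at least 5 and an established symbol, up to 4 detected members per list with the largest absolute ratio, the members with the highest TPM in lists of other cell types, and the reference genes. Other genes are named as examples of a list or in the closing section and were chosen after their values were seen. Some genes that the rule selects are not reported here.

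The alternatives were pseudocounts of 0.1 and 5, no expression filter, a minimum mean TPM of 10, a log2 threshold of 2, the mean in place of the median, 10 expression bins, and 3 other scalings of the libraries. These scalings were the median ratio of genes with a mean TPM of at least 10, an unweighted TMM factor with trims of 30% and 5%, and rescaling without mitochondrially encoded genes and the 20 most abundant genes. Counts with the assembled loci included, counts of protein-coding genes only, and list medians after lowess trends (span 0.3) on transcript length and GC content were removed were added after the data were seen. Length and GC content were those of the longest GENCODE M21 transcript.

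The procedure was tested on simulated data in which a second library was drawn for the 11258 detected genes and 200 genes were changed. The simulated noise was normal, centred on 0 and equal at all expression levels. Its standard deviation was 0.462 on the log2 scale, set from the 25th and 75th percentiles of the real ratios. The 2-fold rule recovered 43 of 50 genes raised by 1.5 on the log2 scale, 42 of 50 lowered by 1.5, and 50 of 50 changed by 3 in each direction. It also took in 343 of 11058 unchanged genes (3.1%). Among 200 simulated lists of 14 genes, 13 stood apart with no shift, 182 with a shift of 0.5 and 200 with a shift of 1. The real ratios had a median of 0.17, and members of real lists can vary together. These rates therefore describe the simulated setting and do not give the error in the real data. The work used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.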

Results

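Gene expression was compared between 4T1 cells grown alone and 4T1 cells that had shared a transwell with M2 macrophages for 3 days. The comparison asks how 4T1 gene expression differs when M2 macrophages, the alternatively activated form of these phagocytes, grow across a permeable membrane. Each group had 1 library and therefore no replicate error, so the values below are single measurements. In the control library 15922 Ensembl genes had a TPM above 0, and in the co-culture library 16198 did. The 20 most abundant rows took 16.7% of the control TPM and 15.7% of the co-culture TPM. Mitochondrially encoded genes took 3.66% and 3.36%. Sequencing depth cannot be read from TPM.

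The 2 libraries were similar over most genes. Across the 11258 detected genes the correlation of log2(TPM + 1) was r = 0.954, which is a correlation across genes within a pair of libraries. The log2 ratios had a median of 0.17, and their 25th and 75th percentiles were -0.14 and 0.48. Of the detected genes 7257 had higher and 3988 had lower values in co-culture. A majority of higher members in a list therefore does not set it apart by itself. By the 2-fold rule 557 genes were higher and 241 were lower in co-culture, so 69.8% of the genes past the threshold were higher. Dividing the co-culture values by the median ratio of abundant genes, a shift of 0.12 on the log2 scale, gave 406 higher and 293 lower, and the share of higher genes was then 58.1%. The genes lower in co-culture included those that respond to endoplasmic reticulum (ER) stress and amino acid shortage. The genes higher in co-culture included those of mitosis, of the hypoxia response and several secreted factors.

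**Figure D1:**
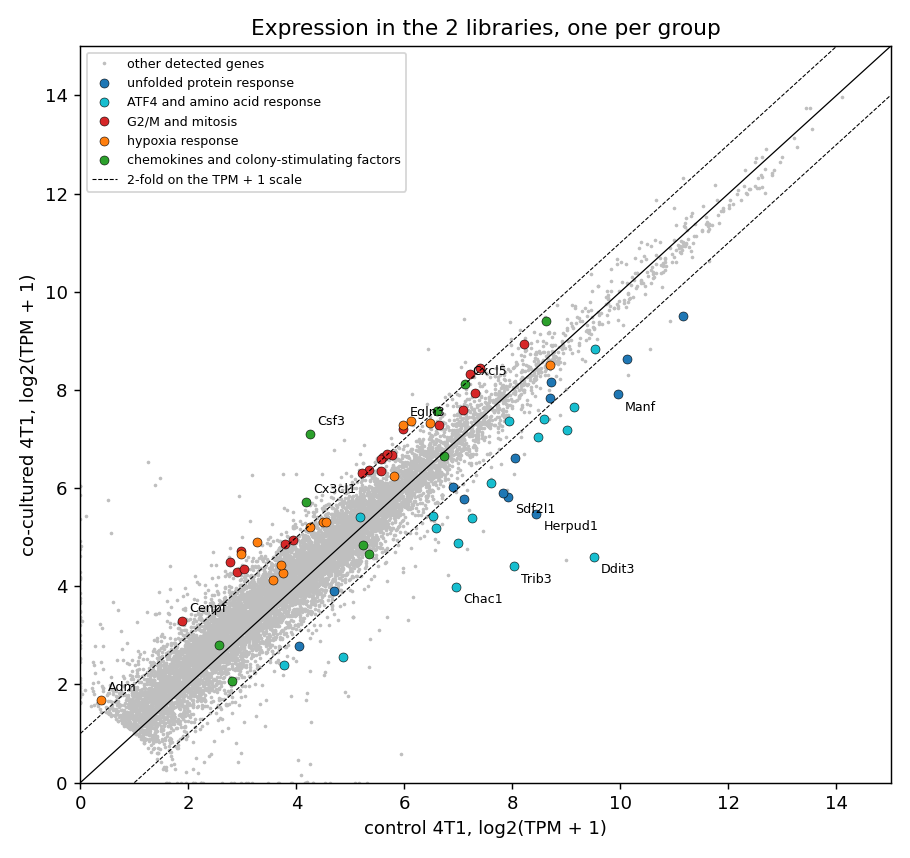
Each point is 1 of the 11258 detected genes, with log2(TPM + 1) in the control library on the x axis and in the co-culture library on the y axis, and members of 5 gene lists in colour. The solid line marks equal values and the dashed lines a 2-fold difference; the detected ATF4 and unfolded protein response genes other than Ddit4 lie below the diagonal, with Ddit3 at 728 TPM in the control and 23.4 TPM in co-culture, while Csf3 lies above it.

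Genes of the unfolded protein response were lower in co-culture, and so were targets of ATF4, the transcription factor of the integrated stress response. All 13 unfolded protein response genes had lower values, 9 of them at least 2-fold, with a list median of -1.44. Of 17 detected genes in the list of ATF4 and amino acid response genes, 14 were at least 2-fold lower and none was 2-fold higher, with a median of -1.48. Both medians lay below those of all 10000 random lists, whose central range was -0.22 to 0.29 for the first list and -0.19 to 0.26 for the second.

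Ddit3, which encodes the stress-induced transcription factor CHOP, had the lowest ratio of either list. It (ENSMUSG00000025408) lies on chromosome 10 of GRCm38 from 127290774 to 127296288 and had 728 TPM in the control and 23.4 TPM in co-culture, a log2 ratio of -4.90. Its span overlaps that of Mars on the opposite strand, and Mars itself had 110 TPM in the control and 78.3 TPM in co-culture. Trib3, a pseudokinase induced by ATF4 and CHOP on chromosome 2 from 152337422 to 152344032, had 260 TPM in the control and 20.2 TPM in co-culture (log2 ratio -3.62). Chac1, which degrades glutathione, had 122 TPM in the control against 14.8 TPM in co-culture. The log2 ratio was -1.83 for Atf4 and -2.31 for Atf3. Among genes of amino acid supply, Asns (asparagine synthetase) had 562 TPM in the control and 201 TPM in co-culture, and Slc7a5, a transporter of large neutral amino acids, had 193 TPM and 67.5 TPM. The serine synthesis gene Phgdh had a log2 ratio of -0.69, and Ddit4 had 35.3 TPM in the control and 41.6 TPM in co-culture.

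In the ER list, Herpud1, a component of ER-associated degradation on chromosome 8 from 94386438 to 94395377, had 347 TPM in the control and 43.7 TPM in co-culture (log2 ratio -2.96). The ratios of Sdf2l1, Manf and Creld2 were -2.09, -2.04 and -1.93. Hspa5, which encodes the main ER chaperone BiP, had 2291 TPM in the control and 724 TPM in co-culture. Hsp90b1 had the smallest difference of the list, with a log2 ratio of -0.56. The list of heat shock protein genes had a median of -0.01, within the random range. Its largest difference was that of Hspa1b, at -2.12, a gene with a near-identical neighbour, Hspa1a, so that its value depends on how shared reads were divided. Hspa8, Hsph1 and Hsp90aa1 had ratios of -0.60, 0.50 and 0.33. The list of NRF2 oxidative stress genes had a median of -0.28, at the 0.46th percentile of random lists. Its lowest members were Hmox1 (haem oxygenase 1; 72.3 TPM in the control and 20.2 TPM in co-culture) and Slc7a11 (cystine transporter; 3.22 TPM and 0.77 TPM). The other 10 of its 12 members were within 2-fold, among them Ftl1 at -0.50 and Srxn1 at -0.36. With a pseudocount of 5 there was 1 member at least 2-fold lower.

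Mitotic genes were higher in co-culture. All 21 genes of the G2/M list had higher values, 15 of them at least 2-fold and none lower, with a median of 1.03 that exceeded all 10000 random lists (central range -0.14 to 0.29). Mki67, the gene of the proliferation marker Ki-67 on chromosome 7 from 135689784 to 135716361, had 6.86 TPM in the control and 25.2 TPM in co-culture (log2 ratio 1.74). The kinetochore motor gene Cenpe had a ratio of 1.73, Cenpf 1.41 and the spindle motor gene Kif11 1.39. Top2a had 147 TPM in the control and 320 TPM in co-culture, and Cdk1 had 168 TPM and 347 TPM. Many of these ratios were close to the threshold, and 7 of the 21 genes were 2-fold higher with the median ratio centring, with the TMM factor and with a pseudocount of 5. The list of G1/S and DNA replication genes had a median of 0.24, within the random range, and none of its 18 members was 2-fold different. The largest ratios there were those of Uhrf1 (0.86), Ccne2 (0.68), Rrm1 (0.64) and Rrm2 (0.63).

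Hypoxia response genes were higher in co-culture. Of 14 detected members 13 had higher values, 5 of them at least 2-fold, and the median of 0.84 exceeded all 10000 random lists. Bhlhe40, a transcriptional repressor, had 6.88 TPM in the control and 24.4 TPM in co-culture. Ankrd37 had 8.68 TPM and 29.0 TPM, and Egln3, a prolyl hydroxylase that acts on HIF, had 61.6 TPM and 155 TPM. Bnip3, a mitophagy receptor, had 68.2 TPM in the control and 165 TPM in co-culture. Adm had 0.30 TPM and 2.23 TPM, near the lower end of detection. Car9 was at 0.38 TPM and 0.39 TPM, and Ndrg1 had a log2 ratio of -0.18.

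Glycolytic genes differed less. Their median was 0.30, at the 98.8th percentile, with 16 of 17 detected members higher (13 with the median ratio centring) and none 2-fold different. The largest ratios were those of Pgam1 (0.91), Aldoc (0.89), Tpi1 (0.73) and Ldha (0.71), which encodes lactate dehydrogenase A. Lipid synthesis genes were also higher. In the cholesterol list 17 of 19 detected members had higher values, 5 of them at least 2-fold, with a median of 0.54 at the 99.6th percentile. Idi1, an isomerase of the mevalonate pathway, had 5.70 TPM in the control and 15.2 TPM in co-culture, and Stard4 and Insig1 had ratios of 1.31 and 1.05. The fatty acid synthesis list had a median of 0.57 at the 99.8th percentile, and all 11 members had higher values (10 with the median ratio centring). Elovl6, a fatty acid elongase, had 2.07 TPM in the control and 9.91 TPM in co-culture, and Scd2, Acly and Fads2 had ratios of 0.80, 0.69 and 0.65. The cholesterol list no longer stood apart when only genes with a mean TPM of at least 10 were kept (94.3rd percentile). With the median ratio centring 3 of its members were 2-fold higher, and with a pseudocount of 5 there was 1.

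Several secreted factors were higher in co-culture. Csf3, which encodes granulocyte colony-stimulating factor, lies on chromosome 11 from 98701263 to 98703629 and had 18.0 TPM in the control and 137 TPM in co-culture (log2 ratio 2.86). In the list of chemokines and colony-stimulating factors 6 of 10 detected members had higher values, 2 of them at least 2-fold, and the median of 0.52 lay at the 99.4th percentile. The share of higher members was below that among all detected genes. Cx3cl1 (fractalkine) had 17.2 TPM in the control and 51.5 TPM in co-culture, Cxcl5 had 139 TPM and 277 TPM, and Ccl2, a monocyte attractant, had 95.9 TPM and 190 TPM. Ccl7, Ccl20, Ccl5 and Csf1 had ratios of -0.72, -0.68, -0.41 and -0.09. The acute-phase and complement list had only 3 detected members. These were C3, with 27.3 TPM in the control and 74.4 TPM in co-culture, Saa3 with 6.01 TPM and 13.4 TPM, and Lcn2 with 207 TPM and 349 TPM. Their median of 1.04 lay at the 99.7th percentile, which became the 81st when undetected members were kept. With the median ratio centring 1 of them was 2-fold higher.

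Genes of matrix proteolysis and of the immediate-early response were also higher in co-culture as groups. In the list of extracellular proteases and their inhibitors 13 of 15 detected members had higher values (11 with the median ratio centring), 3 of them at least 2-fold, with a median of 0.46 at the 99.4th percentile. Plau (urokinase) on chromosome 14 from 20836660 to 20843385 had 24.9 TPM in the control and 108 TPM in co-culture. Mmp13 (collagenase 3) had 3.92 TPM and 15.4 TPM, Mmp14 had 33.7 TPM and 69.2 TPM, and Mmp10 had 9.59 TPM and 19.0 TPM. In the immediate-early list 12 of 17 detected members had higher values, 4 of them at least 2-fold, with a median of 0.51 at the 99.7th percentile. The share of higher members was close to that among all detected genes. Ier3 had 136 TPM in the control and 694 TPM in co-culture. Dusp6, a phosphatase of ERK, had 22.9 TPM and 49.9 TPM, Egr1 had 1.25 TPM and 5.34 TPM, and Egr3 had 0.33 TPM and 2.06 TPM. Myc was among the members with lower values, at 189 TPM in the control and 103 TPM in co-culture. The list lay within the random range among genes with a mean TPM of at least 10 (94.8th percentile), and with a pseudocount of 5 there was 1 member 2-fold higher. NF-kB and inflammatory cytokine genes had a median of 0.13, within the random range, with Tnfaip3 (A20) at 4.35 TPM and 20.7 TPM, Nfkb1 and Nfkbia at ratios of 0.64 and 0.58, and Ptgs2 at -0.51.

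Most markers of macrophages were at or near 0 in both libraries. Of 20 macrophage and myeloid markers only Cd68 and Cd14 were detected. Cd68 had 57.7 TPM in the control and 27.8 TPM in co-culture, and Cd14 had 8.87 TPM and 12.4 TPM. Lyz2, an abundant macrophage transcript, was listed at 0 in the control and had 0.04 TPM in co-culture. Tyrobp, Fcer1g and Adgre1 were listed at 0 in both libraries, and Aif1 had 0.27 TPM in co-culture. None of 13 M2 markers was detected. Ccl17 had the highest value among them, at 0.53 TPM and 0.98 TPM, and Mrc1 had 0.05 TPM and 0.08 TPM. Of 13 lymphocyte and granulocyte markers only S100a8 was detected, at 0.60 TPM in the control and 4.66 TPM in co-culture, while S100a9 was listed at 0 in both. Fibroblast markers were detected for 2 of 12 genes, namely Pdgfra at 5.60 TPM and 10.2 TPM and Tagln at 2.09 TPM and 1.36 TPM.

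Epithelial and mesenchymal lists did not stand apart. The epithelial list had a median of 0.36 over 7 detected members, and Krt8 and Krt18 were abundant in both libraries, with Krt8 at 548 TPM and 630 TPM. In this list 8 of 15 markers were not detected, among them Epcam and Cdh1. Its largest ratio was that of Krt19, at 0.18 TPM in the control and 2.64 TPM in co-culture, and Tjp1, Cldn3 and Ocln had ratios of 0.78, 0.72 and 0.36. This list passed the upper limit when the mean replaced the median (97.9th percentile). The mesenchymal list had a median of 0.28 over 9 detected members. S100a4 was the only one at least 2-fold higher, with 2291 TPM in the control and 5110 TPM in co-culture, and Zeb2, Itga5 and Foxc2 had ratios of 0.53, 0.43 and 0.29. Vim had 4590 TPM and 4066 TPM. The stem-cell associated list had a median of 0.41, with the integrin gene Itgb3 at 13.2 TPM in the control and 45.9 TPM in co-culture and ratios of 0.92 for Cd24a, 0.86 for Itga6 and 0.51 for Cd44.

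Other signalling lists lay within the random range. The interferon list had a median of -0.06 over 11 detected members, with Isg15 at 25.7 TPM in the control and 14.5 TPM in co-culture. Oasl2, the only member 2-fold higher, had 0.51 TPM and 2.11 TPM, a difference below 2-fold with the median ratio centring. Stat2 and Oasl1 had ratios of 0.76 and -0.47. The MHC class I list had a median of 0.07, with Psmb9, Psmb8, Tapbp and Tap1 at 0.82, 0.75, 0.72 and 0.44. That median was -0.05 with the median ratio centring and with the TMM factor. The list of immune checkpoint ligands, which also holds enzyme genes, had a median of 0.45 over 5 detected members. The enzyme gene Nt5e (CD73) had the largest ratio, 0.95. Pvr, Cd276 and Lgals9 had ratios of 0.63, 0.45 and 0.21, and Cd274, which encodes PD-L1, was not detected, at 0.51 TPM and 0.68 TPM. The TGF-beta list had a median of 0.16, with Thbs1 (thrombospondin 1) at 5.83 TPM in the control and 18.3 TPM in co-culture and ratios of 1.25 for Tgfb3, 0.82 for Tgfb1 and -0.87 for Id3. Angiogenic factors had a median of 0.43, with 8 of 11 detected members higher and 3 lower. Pgf (placental growth factor) had 7.13 TPM in the control and 17.1 TPM in co-culture, and Pdgfb, Pdgfa and Angptl2 had ratios of 0.88, 0.79 and 0.59. Among the lower members, Vegfa and Vegfb had ratios of -0.30 and -0.19. The list of JAK-STAT feedback genes, which also holds receptor and STAT genes, had a median of 0.37. Cish, Il4ra, Stat6 and Pim1 had ratios of 0.71, 0.51, 0.44 and 0.43. The 3 detected Wnt targets had a median of 0.61, with Ccnd1 (cyclin D1) at 362 TPM and 561 TPM, Tcf7 at 0.61 and Znrf3 at 0.11. The p53 targets had a median of -0.06, with Cdkn1a (p21) at 9.26 TPM and 27.5 TPM, Bbc3 (PUMA) at 23.3 TPM and 8.26 TPM, Plk2 at -0.95 and Aen at -0.56. The Notch list had a median of 0.62 over 5 detected members, of which Notch1 had the largest ratio, 4.73. Nrarp and Notch2 had ratios of 0.87 and 0.62. Hes1, a Notch target like Nrarp, had 9.86 TPM in the control and 5.27 TPM in co-culture, so these targets differed in opposite directions.

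Ribosomal protein genes had a median of -0.24, with all 23 lower and none 2-fold different, at the 0.46th percentile. Rpl3 and Rpl32 had ratios of -0.39 and -0.36. The list lay within the random range for the mean in place of the median (percentile 3.4) and after trends on transcript length and GC content were removed (4.42). The mean and the corrected median were also -0.24, and the lower end of the random range was -0.26 and -0.25 there, against -0.20 before. The 13 reference genes had a median of 0.30 at the 97.8th percentile, and 0.07 at 88.1 after the same correction. Eef1a1 had the lowest ratio, -0.23, and Tfrc the highest, with 18.5 TPM in the control and 38.0 TPM in co-culture, a difference below 2-fold with each of the 3 other scalings. The ratio was 0.75 for Hprt, 0.64 for Actb, 0.54 for Ywhaz, 0.30 for Pgk1 and -0.05 for Ppia. It was 0.41 for Polr2a, 0.40 for Gusb and 0.14 for Tbp. The ratio of Tubb5 was 0.05, and it was -0.06 with the median ratio centring. Nuclear genes of oxidative phosphorylation had a median of -0.10, with Cox7a2 at 0.55, Ndufv1 at -0.33, Cox6a1 at -0.30 and Cox4i1 at -0.24. Fatty acid oxidation genes had a median of 0.19, with Ppard at 0.61, Cpt2 at 0.55, Cpt1a at 0.50 and Acadm at 0.42. Mitochondrially encoded mRNAs had a median of 0.13, and their ratios ran from -0.68 for mt-Atp6 to 1.06 for mt-Co3, with mt-Co2 at 0.64 and mt-Nd4l at 0.63. These 3 lists lay within the random range, and reads of mitochondrial genes are shared with nuclear copies. The list of nuclear-retained and non-polyadenylated RNAs had a median of 0.82, at the 99.99th percentile, and its largest ratios were those of replication-dependent histone genes such as Hist1h2bb (0.26 TPM in the control and 3.16 TPM in co-culture) and Hist2h2ac (1.24 TPM and 4.76 TPM). Hist1h3b and Hist1h4d had ratios of 1.27 and 1.24. None of its members was 2-fold higher with a pseudocount of 5, and histone genes share reads with near-identical copies. Of the 33 lists with at least 3 detected members, 11 stood apart upwards and 4 downwards, against 1.65 for lists of unrelated genes. Members of a list can vary together, and some lists share genes, such as Pgk1. The number of lists that stood apart is therefore no measure of an excess over chance.

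**Figure D2:**
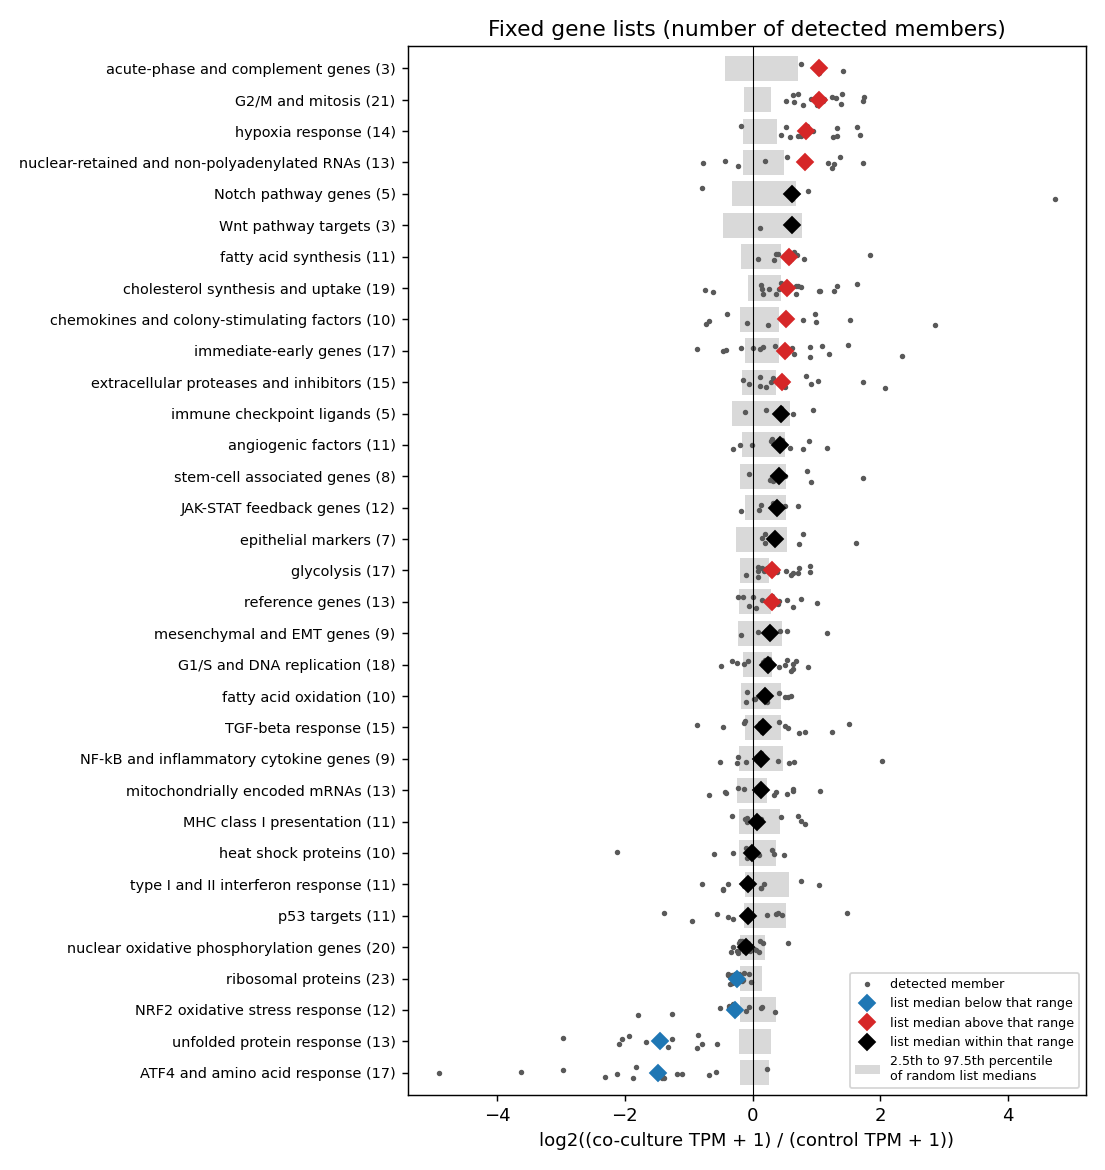
Each row is 1 of the 33 fixed gene lists with at least 3 detected members. The x axis is the log2 ratio of co-culture to control, dots are members, diamonds are list medians and grey bars span the central range, between the limits set for standing apart, of the medians of 10000 random lists matched on expression; the unfolded protein response (-1.44) and ATF4 (-1.48) medians lie far to the left and the G2/M (1.03) and hypoxia (0.84) medians to the right.

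The 24 genes with the most extreme ratios were a mixed group. Besides Csf3 and Ier3, the 12 highest included Notch1, the receptor gene on chromosome 2 from 26457903 to 26516663, with 1.79 TPM in the control and 72.9 TPM in co-culture. Garem1 had 0.42 TPM and 53.1 TPM, Slc15a4 had 8.10 TPM and 76.5 TPM, Lgals2 had 0.53 TPM and 11.8 TPM, and Agbl4 had 1.73 TPM and 13.8 TPM. The remaining 5 were the histone genes Hist1h4n and Hist1h2ah, the Pgk1 copy Pgk1-rs7, and the small RNA genes Rnu1b6 and Scarna6. Hist1h2ah, Rnu1b6 and Scarna6 were listed at 0 in the control. Besides Ddit3, Trib3 and Chac1, the 12 lowest included Poln, with 59.9 TPM in the control and 0.49 TPM in co-culture, Ccdc148 with 17.3 TPM and 0.01 TPM, and Pde9a with 15.9 TPM and 0.12 TPM. Angptl6 had 29.9 TPM and 2.38 TPM, Tyw3 had 39.8 TPM and 4.10 TPM, and Cdsn had 18.3 TPM and 1.37 TPM. Snurf, Snora23 and Snora73a were listed at 0 in co-culture. Of the 24 genes 11 were below 1 TPM in one of the libraries. The spans of 10 overlapped another detected gene, so their values may depend on how reads were assigned, though overlap of spans does not show shared reads. These 10 were Ddit3, Notch1, Lgals2, Poln, Angptl6, Tyw3, Snurf, Snora23, Snora73a and Scarna6. Histone, small RNA and Pgk1-rs7 values are uncertain for the further reason that near-identical copies share reads.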

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

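The share of TPM in assembled loci without a gene identifier was examined only after the data were seen. These 884 rows, which the gene-level comparisons do not use, took 4.38% of the control TPM and 6.47% of the co-culture TPM. Of the 651 loci with a mean TPM of at least 1, 551 had higher values in co-culture, 214 of them at least 2-fold, and 36 were at least 2-fold lower. Their median log2 ratio was 0.77, against 0.17 for the detected Ensembl genes. The loci carry no coordinates in the table used here.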

How the results depend on the processing

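The counts of protein-coding genes only, the counts with assembled loci and the removal of length and GC trends were chosen after the data were seen. Against 557 genes higher and 241 lower, a pseudocount of 0.1 gave 886 higher, a pseudocount of 5 gave 199 higher and 129 lower, a minimum mean TPM of 10 gave 244 and 120, and a log2 threshold of 2 gave 75 and 66. Counting protein-coding genes only gave 156 lower. Each of these settings changes by construction which genes can pass, and the counts under the remaining alternatives were within 1.5 times. Among the 33 list medians and 173 named genes, none that stood apart or passed the threshold changed sign under the alternatives run. Of 327 alternative list medians 2 moved by more than 1.5 times, both without the expression filter. Of 982 alternative values of named genes 55 did, 25 with a pseudocount of 0.1 and 30 with a pseudocount of 5. Further lists passed a limit in some settings, and the cause was not tested. The Notch list passed the upper limit with a pseudocount of 0.1 (97.8th percentile) and with the mean (99.2), the stem-cell list without a filter (99.6) and with the mean (97.9), and the epithelial list without a filter (97.8). The p53 targets passed the lower limit at a mean TPM of at least 10 (0.96). The reference genes lay within the limits in 4 settings, at percentiles from 88.1 to 97. No paired analysis was possible because each group holds 1 library. Depth is unknown from TPM, so the reach of counting error cannot be computed, and low values carry the most of it.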

Other observations

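The 6 further gene lists were chosen after the fixed lists had been read, but before their own values were seen. The tests of library scaling, of culture conditions and of macrophage RNA, the counting of ties in the test of overlapping genes, the count of short RNAs and the alternatives run for the 6 lists were chosen after the results were seen. The question in each case was whether other members of a programme, absent from the fixed lists, differed in the same direction. Aminoacyl-tRNA synthetase genes, several of which ATF4 is known to regulate, had a median log2 ratio of -0.52 and lay below all random lists (percentile 0). Aars had 147 TPM in the control and 46.1 TPM in co-culture, Sars had 468 TPM and 178 TPM, and 19 of 20 members had lower values. Further ER protein-quality genes had a median of -0.35 (percentile 0), with Syvn1, an ER ubiquitin ligase, at 39.2 TPM and 15.1 TPM. Of their 21 detected members 19 had lower values, 3 of them at least 2-fold. That 2-fold count was 4 with the median ratio centring and 1 with a pseudocount of 5. Further mitotic genes had a median of 0.94 (percentile 100), with all 23 higher, 10 of them at least 2-fold (6 with the median ratio centring or the TMM factor and 4 with a pseudocount of 5), and Ckap2l at 17.5 TPM and 44.6 TPM. Further hypoxia genes had a median of 0.51 (percentile 99.75), with Ak4 at 7.12 TPM and 24.4 TPM. All 16 detected members were higher (14 with the median ratio centring), 3 of them at least 2-fold. With a pseudocount of 5 there was 1 at least 2-fold higher. Each of the 6 lists stayed past its limit under every alternative run. These results are consistent with a wider ATF4 and ER programme, a wider mitotic programme and a wider hypoxia programme that differ between these libraries.

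Host genes of small nucleolar RNAs were lower in co-culture. Snhg5, Snhg12, Snhg1 and Snhg15, noticed among the lowest genes, had log2 ratios of -2.40, -1.95, -1.75 and -1.68. The other host genes, tested as a separate list, had a median of -0.48 over 9 detected members (percentile 0.09), with Gas5 at 296 TPM in the control and 102 TPM in co-culture and Zfas1 at 192 TPM and 72.3 TPM, while Snhg14 was higher, at 4.40 TPM and 9.67 TPM. Because Myc was lower in co-culture, ribosome biogenesis genes were tested. Their median was -0.23 (percentile 0.27), with Nop56 at 355 TPM and 191 TPM and 15 of 20 members lower, none of them 2-fold (19 lower and 1 of them 2-fold with the median ratio centring or the TMM factor). Trp53 had 94.2 TPM in the control and 25.9 TPM in co-culture, and Spp1 (osteopontin) had 390 TPM and 716 TPM.

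The most prominent pattern was the lower expression of the unfolded protein response and ATF4 genes. Library scaling is argued against, because a scale factor moves all genes alike and so moves the random lists too. The median ratio of all detected genes was 0.17, in the other direction. That median decides less, since TPM fixes the library totals and so limits how far it can move. A trend on transcript length or GC content is also argued against. The log2 ratio correlated with transcript length across genes (Spearman's rho 0.28, genes not being independent replicates), but after the length and GC trends were removed the median of the 30 genes was -1.54, against -1.46 before, and still below all random lists (percentile 0). What stays open is whether the difference comes from the macrophages or from culture conditions other than the macrophages, such as medium or density. Any other difference between single cultures or single libraries stays open as well. With 1 library per group these cannot be told apart.

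The higher expression of mitotic genes was weighed in the same way. After length and GC trends were removed the G2/M median was 0.90, against 1.03 before, and still above all random lists (percentile 100), which argues against transcript length and GC content as the whole cause. RNA from macrophages in the co-culture library is argued against by the median of 0 TPM over the 20 macrophage and myeloid markers, with Lyz2 at 0.04 TPM. Of these markers 2, Cd68 and Cd14, were detected in the control as well. A difference in cell density or growth phase between the cultures was not tested and remains open beside an effect of the macrophages. So does any other difference between single cultures or single libraries.

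The most extreme ratios may partly come from read assignment, which the values leave open, and no biological explanation was tested. Of the 24 genes 41.7% overlapped another detected gene, against a mean of 21.8% in random sets matched on expression (central range 8.33% to 41.7%), and 97.44% of these sets had a smaller share and 1.71% an equal one, so the counting of ties decides whether the upper limit set before for reads shared with overlapping genes was passed. All 12 overlapping partners were within 2-fold on the log2(TPM + 1) scale, which decides little where a short gene lies in a long partner. Beside Ddit3, Mars had 110 TPM in the control and 78.3 TPM in co-culture. Haus3, beside Poln, had 4.12 TPM and 7.04 TPM. Mars is itself a tRNA synthetase gene, and its log2 ratio of -0.49 was close to the median of that list, -0.52. Its lower value therefore does not by itself point to reads shared with Ddit3. The other 14 genes overlapped no detected annotated gene, and overlap with the assembled loci was not tested because these carry no coordinates here. Short or alternative transcript models also stay open, because the median length of the shortest annotated transcript, 496 nt against 476 nt in random sets (63.4th percentile) and set before to count against them at this level, shows neither a subset of genes nor which model was used, and 5 of the 24 are RNAs under 300 nt, against at most 2 in the random sets.

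Some epithelial genes were at or near 0 in both libraries. Epcam, Esrp1 and Cldn7 were listed at 0, and Cdh1, which encodes E-cadherin, had 0.04 TPM in the control and 0.01 TPM in co-culture. Twist1 had 26.5 TPM and 32.3 TPM, while Zeb1 and Snai2 of the mesenchymal list were listed at 0 in both libraries. The epithelial keratin gene Krt8 had 548 TPM in the control and 630 TPM in co-culture. The near absence of Cdh1, Epcam, Esrp1 and Cldn7 in cells labelled as a carcinoma line is a reason for caution about that label. The identity of the cells as 4T1 rests on the labels and was not assessed here.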
